A study of Caenorhabditis elegans with 12 samples.

How the data were processed

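Total RNA of whole worms, from bleach-synchronised liquid cultures collected at the L4 stage, was labelled as biotinylated cRNA and hybridised to Affymetrix C. elegans arrays. The 12 arrays form 4 groups of 3: wild type (N2) and atfs-1(tm4525), each on control RNAi and on spg-7 RNAi. The values used are probe-set signal intensities as deposited by the authors, on a linear scale. The submitters' processing notes name MAS5 without a version, and its settings were not stated. That the authors scaled the arrays to a common level was read from the values: the mean without the lowest and highest 2% of probe sets was 500.1 to 500.2 on each array. No value was missing. Detection calls and raw scans were not used here.

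Each table held 22625 probe sets. The 77 Affymetrix control probe sets were set aside, and of the other 22548 the annotation of the array gave 1 gene name for 20766, several for 887 and none for 895. Values were floored at 1, which applied to 0.509% of them, and taken to log2. The 40% of probe sets with the lowest mean log2 signal over all arrays were left out, a level of 6.25 (signal 76.0) that left 13529. Each gene was then represented by its brightest probe set with a single gene name, giving 10385 genes, of which 3250 were measured through a probe set marked s and 463 through one marked x, types that can bind transcripts of more than 1 gene. No further scaling between arrays was applied.

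A linear model with 1 mean per group was fitted over the 12 arrays with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with moderated variances and a variance trend; 8 residual degrees of freedom and a median of 3.71 prior ones gave 11.7 in total. The 5 comparisons were spg-7 RNAi against control RNAi in wild type and in the mutant, the difference between these 2 responses (mutant minus wild type), and mutant against wild type on each RNAi. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison; p values and adjusted p values for single genes are from limma. SE is the standard error of a log2 difference from that model, and group signals are means with SD over 3 arrays. Control probe sets and RNA quality ratios were compared by exact two-sided permutation tests, whose smallest p is 0.1 for 3 arrays against 3 and 0.005 within both genotypes together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

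Before the data were examined, 26 gene lists were written from gene names and families. Lists for mitochondria and metabolism were mitochondrial chaperones and proteases, mitochondrial protein import, mitochondrial dynamics and mitophagy, glycolysis, the tricarboxylic acid cycle, the nuclear-encoded respiratory chain and transcripts of mitochondrial DNA. Others were mitochondrial and cytosolic ribosomal proteins, the proteasome and fatty acid desaturation and oxidation. Stress and defence lists were innate immunity, cytochrome P450 enzymes, glucuronosyltransferases, glutathione S-transferases, oxidative stress defence, the endoplasmic reticulum unfolded protein response, cytosolic heat shock and stress-linked regulators. Tissue and stage lists were vitellogenins, major sperm proteins, oocyte and embryo markers, cuticle collagens, and muscle, neuron and intestine markers. The list of mitochondrial DNA transcripts matched 0 genes, so 25 were tested, and 1 name in the chaperone list was not matched. Each list was tested against all other genes with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the data. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the members of 1 list.

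The genes named were fixed by a rule at the same time: spg-7, atfs-1, hsp-6 and hsp-60 always; per comparison up to 10 called genes in each direction with the largest log2 change whose groups did not overlap; and per list up to 4 members with the largest change. Which of the eligible list members were named was decided after their values were seen. The thresholds, the filter, the comparisons and most alternatives were also fixed at that time. The alternatives were quantile normalisation, centring each array on its median, adding 32 before log2, no filter, leaving out the lowest 60% and another choice of probe set. For the model they were array weights, a fit to the groups of a comparison only, no variance trend, the replicate number as a block, a minimum of 2-fold, an adjusted p under 0.01 and leaving out each array. Added after the data had been seen were leaving out 2 wild-type arrays together, the oocyte and embryo marker level as a covariate, and scaling to the hybridisation control probe sets.

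The calling was tested on simulated data, 5 runs with 200 changed genes each. Of 2-, 4- and 8-fold changes in the wild-type response 16.4%, 69.0% and 87.3% were called, and of changes of that size in the difference between responses 1.19%, 37.6% and 64.2%. False calls made up 5.44% of all calls in the simulated wild-type response. In the mutant response of the same runs, where no gene had been changed, at most 1 gene was called per run. At an unadjusted camera p under 0.05 a shifted list was called in 5 of 5 runs and an unshifted one in 0. Simulated genes were independent of each other, with the same spread in every group. The runs therefore do not test the preset correlation between genes or the effect of arrays of unequal noise. Replicate numbers are shared between groups by the labels, which do not say that arrays with the same number were grown or processed together, so the main fits had no pairing. Between the 2 mutant groups the deviations from the group means correlated in all 3 same-numbered pairs of arrays (r = 0.286, 0.422 and 0.525). The numbers were therefore taken to pair the arrays in the mutant response, from the data and not the labels. A value with the replicate block is given where it changed a call there. Elsewhere the lowest r of a same-numbered pair was -0.101 in the wild-type response, -0.462 between genotypes on control RNAi and -0.0911 on spg-7 RNAi. The highest was 0.577, 0.121 and 0.663. With 3 pairs each a pairing was not settled there, and none was taken.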

Results

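RNA from whole Caenorhabditis elegans was measured on 12 Affymetrix expression arrays in 4 groups of 3. Wild-type (N2) worms and worms carrying the atfs-1 allele tm4525 were each grown on bacteria for control RNAi or for spg-7 RNAi and collected at the last larval stage, L4. The gene atfs-1 encodes a bZIP transcription factor of the mitochondrial unfolded protein response, and spg-7 encodes a subunit of a protease of the mitochondrial inner membrane whose knockdown is a common way to stress mitochondria. The title of the series poses the question whether ATFS-1 carries a protective transcription programme under such stress. The deposited signal had a median of 112 to 159 per array and a trimmed mean of 500.1 to 500.2 on every array. Pearson's r across probe sets between replicates was 0.867 to 0.920 in wild type on control RNAi and 0.879 to 0.917 on spg-7 RNAi. In the mutant it was 0.935 to 0.946 on control RNAi and 0.922 to 0.939 on spg-7 RNAi. Probe sets for 10385 genes were tested, and the number of arrays limits the precision of every value.

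Genes of egg yolk, sperm and oocytes, whose RNA appears as the germ line matures, differed between replicates. In wild type on control RNAi the median log2 signal of the vitellogenins, the yolk proteins, was 6.46 on replicate 1, 14.48 on replicate 2 and 13.96 on replicate 3. The major sperm proteins stood at 11.52 on that first array and at 14.26 and 14.41 on the others. Oocyte and embryo markers had a median of 8.63, 11.28 and 12.36 on the 3 wild-type spg-7 RNAi arrays. The vitellogenins had a median of 13.01, 10.95 and 13.79 on the 3 mutant spg-7 RNAi arrays. A measure of RNA quality differed with the RNAi treatment: the log2 ratio of the 3' to the 5' actin control probe sets was 0.84 ± 0.01 (SD, n = 3) in wild type on spg-7 RNAi against 0.53 ± 0.10 on control RNAi, and 0.61 ± 0.07 against 0.44 ± 0.04 in the mutant. The exact two-sided permutation test within genotypes gave p = 0.005 for the mean difference of 0.24, with 6 of 6 spg-7 RNAi arrays above every control array of their genotype, the smallest p that it allows, and 0.025 after adjustment over 5 control genes. For glyceraldehyde-3-phosphate dehydrogenase the same exact test gave a difference of -0.14 and an adjusted p of 0.0625, and for the other 3 control genes the adjusted p was 0.712 to 0.93.

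**Figure D1:**
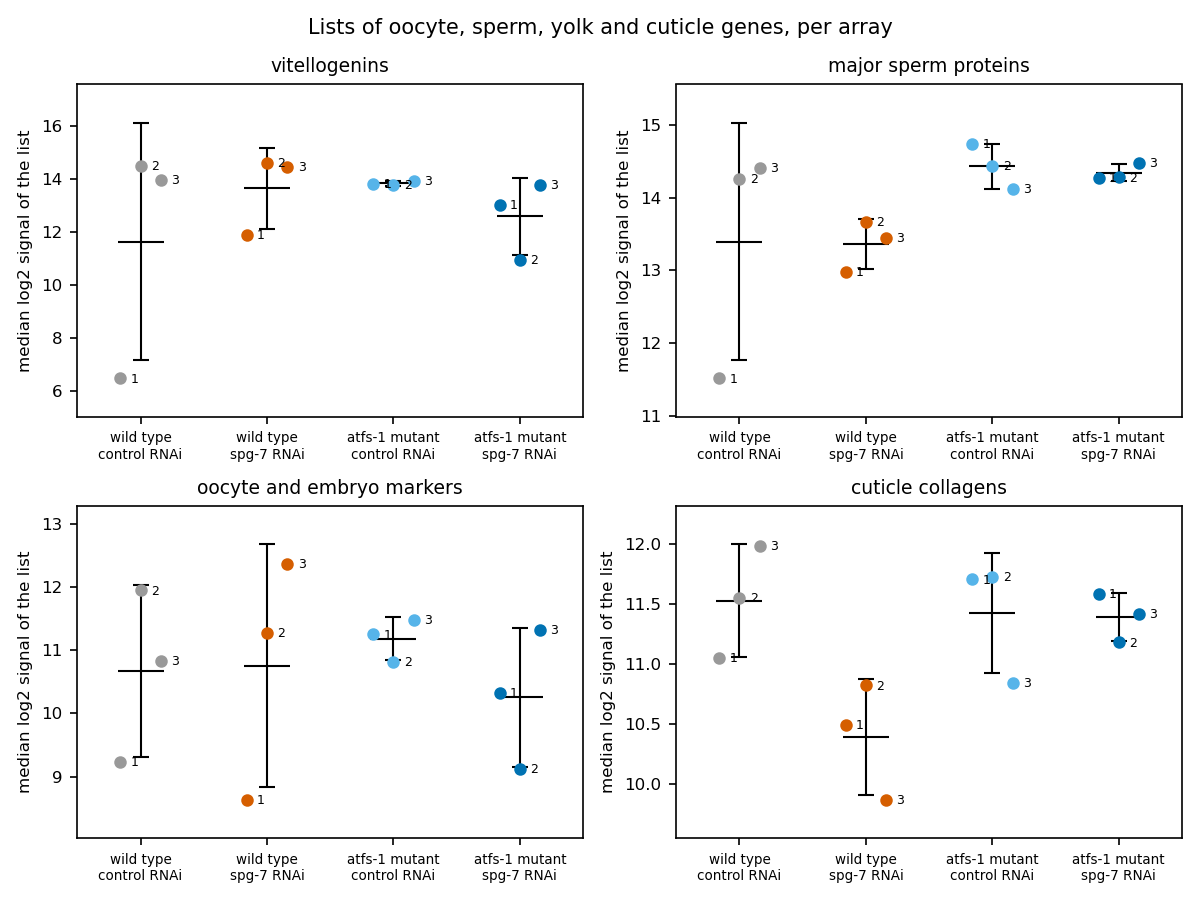
Median log2 signal of the yolk, sperm, oocyte and cuticle collagen lists on each array (points, numbered by replicate), with the mean and SD of the 3 arrays of each group (bars). Wild-type control RNAi replicate 1 had the lowest vitellogenin (6.46) and sperm protein (11.52) medians of the 12 arrays.

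The signal of the targeted gene spg-7 was higher, not lower, on spg-7 RNAi in both genotypes. In wild type it stood at 753 ± 302 on control RNAi and at 14356 ± 7577 on spg-7 RNAi (mean signal ± SD, n = 3 arrays), an 18.3-fold rise on the log2 scale. In the mutant it stood at 383 ± 68.5 and at 17958 ± 8123, a log2 rise of 5.46. Limma gave adjusted p values of 4.1e-04 and 1.0e-04 for these rises, and the difference between them was 1.27 ± 0.64 (log2, SE) with an adjusted p of 0.816. The depth of the knockdown can therefore not be read from this probe set. Its signals do not overlap between the RNAi treatments, which argues against single swapped arrays, but an exchange of all labels would look the same. Directions given below follow the labels of the arrays. The atfs-1 signal rose in wild type from 411 ± 41.98 to 834 ± 219, a log2 change of 0.99 ± 0.25 (SE) with an adjusted p of 0.0469. This call was lost in 10 of the 12 fits without 1 array, in which the adjusted p was 0.0609 to 0.128, and was kept without wild-type control RNAi replicate 1 or wild-type spg-7 RNAi replicate 2. In the mutant atfs-1 stood at 438 ± 74.1 on control RNAi and 588 ± 31.5 on spg-7 RNAi (limma adjusted p = 0.618), so the allele left a signal at this probe set. The difference between the 2 responses was -0.55 (adjusted p = 0.876). This probe set is marked s, a type that can bind transcripts of more than 1 gene. Its position relative to the tm4525 change was not checked, so whether atfs-1 transcript remained in the mutant cannot be read from it.

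The mitochondrial chaperone genes hsp-6 and hsp-60, the usual reporters of the mitochondrial unfolded protein response, did not pass the test in either genotype. In wild type hsp-6 was at 4076 ± 1366 on control RNAi and 5458 ± 1692 on spg-7 RNAi, and in the mutant at 4697 ± 259.6 and 5523 ± 673 (n = 3 each). Its log2 differences were 0.44 and 0.23, with limma adjusted p values of 0.447 and 0.782. For hsp-60 the 4 group means were 5035 ± 389, 3777 ± 1560.4, 3252 ± 223 and 2587 ± 273, with log2 differences of -0.49 (adjusted p = 0.323) and -0.33 (adjusted p = 0.696). A further probe set of hsp-6 gave 0.33 and 0.00, and a further probe set of hsp-60 gave 0.32 in wild type, opposite in sign to the first, and -0.38 in the mutant; none of these passed the test.

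**Figure D2:**
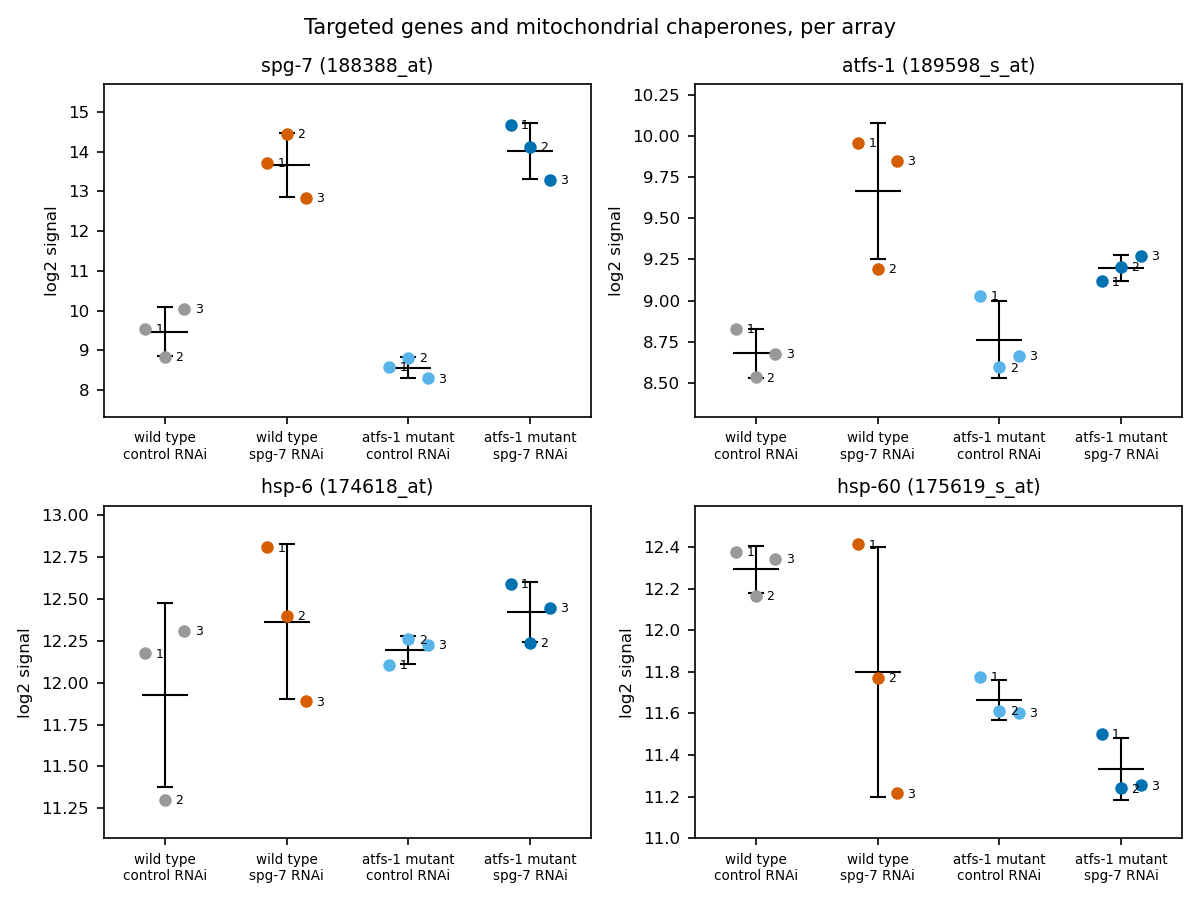
Log2 signal of spg-7, atfs-1, hsp-6 and hsp-60 on each of the 12 arrays (points, numbered by replicate), with the mean and SD of each group of 3 (bars). All 6 spg-7 RNAi arrays lie above all 6 control arrays for spg-7, while the groups overlap for hsp-6.

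The first comparison asks how wild-type worms respond to spg-7 RNAi. Among the 10 largest rises were 4 cytochrome P450 genes and 1 glucuronosyltransferase gene. The cytochrome P450 gene cyp-14A4 went from a signal of 29.9 ± 11.8 to 3901 ± 1758 (SD, n = 3), and cyp-33C8 from 169.8 ± 36.8 to 8913 ± 1811, a 52.6-fold rise. The glucuronosyltransferase gene ugt-19 rose 23.3-fold, from 150.1 ± 12.9 to 3499 ± 219. The beta-tubulin gene tbb-6 rose 56.5-fold, from 206 ± 31.1 to 12055 ± 4456, and the largest falls were in wrt-4, a hedgehog-related gene (14.8-fold, from 2775 ± 654 to 226 ± 139), and K01D12.9 (10.8-fold, from 1448 ± 527 to 133 ± 42.9).

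The 10 genes with the largest rises included cyp-14A4, cyp-13A8, cyp-13A5 and the C-type lectin gene clec-17, with limma adjusted p values of 5.5e-06, 2.1e-04, 6.1e-04 and 0.0033. The control signal of these 4 genes and of C08E8.4 lay under the filter level of 76.0, so the size of their changes is uncertain. With 32 added before log2 their log2 changes were 5.92, 5.69, 5.35, 4.74 and 4.02. The adjusted p of C08E8.4 was 0.0011. The other 5 were tbb-6 (log2 5.82, and 5.61 with 32 added), cyp-33C8 (5.72 and 5.47), R08F11.4 (5.64 and 5.196), Y41C4A.32 (4.73 and 4.304) and ugt-19 (4.54 and 4.28), with adjusted p from 1.6e-06 to 8.4e-04. With 32 added tbb-6 and cyp-33C8 thus stood above cyp-13A5 and clec-17. Single arrays moved 3 of these values by over 1.5-fold without ending a call. The log2 value of clec-17 was 4.83 without wild-type control RNAi replicate 3 and 6.90 without replicate 1. That of cyp-13A5 was 6.95 without wild-type control RNAi replicate 1 and 6.85 without wild-type spg-7 RNAi replicate 1, and that of Y41C4A.32 was 4.04 and 5.39 without wild-type control RNAi replicates 1 and 2. Among the falls, wrt-4 (-3.88, adjusted p = 0.0077), K01D12.9 (-3.43, 8.4e-04), wrt-6 (-2.59, 0.0118) and K01D12.8 (-2.58, 0.0059) kept their calls whichever array was left out, with wrt-4 at -3.17 without wild-type spg-7 RNAi replicate 3. The other falls among the 10 largest were less stable: the calls of F57H12.6 (-3.32), F20B10.3 (-2.74), cbs-2 (-2.72), cht-2 (-2.58), W04A4.2 (-2.67) and W03A5.1 (-2.75) were lost in 1, 3, 3, 3, 7 and 10 of the 12 fits without 1 array, at adjusted p up to 0.137. Single arrays moved 4 of these falls by over 1.5-fold: F57H12.6 to -2.67 and -4.19 without wild-type control RNAi replicates 1 and 2, F20B10.3 to -3.38 without wild-type control RNAi replicate 2, cbs-2 to -3.36 without wild-type spg-7 RNAi replicate 2, and W03A5.1 to -3.71 and -1.82 without wild-type spg-7 RNAi replicates 1 and 3. On spg-7 RNAi the signal of W03A5.1, F20B10.3, cbs-2, W04A4.2, K01D12.8 and cht-2 lay under the filter level. With 32 added their falls were -1.37, -2.26, -1.59, -2.12, -1.88 and -1.66.

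The 5 lists of detoxification and defence genes had higher medians in wild type, called at the preset correlation only. Wild-type spg-7 RNAi replicate 3 stood apart in 3 of them. Its median log2 signal was 9.32 for innate immunity, against 8.48 to 9.21 on the wild-type control arrays, 10.497 for oxidative stress defence (10.36 to 10.503) and 9.19 for glutathione S-transferases (9.39 to 9.87). Of 32 innate immunity genes 10 rose and none fell (17 and 0 adjusted over the list alone), among them irg-2, an infection response gene (log2 4.32, and 3.45 without wild-type control RNAi replicate 1; 3.402 with 32 added, as its control signal was under the filter level), the lectin gene clec-4 (log2 3.46, from 526 ± 288 to 5620.5 ± 2354) and the antimicrobial peptide gene abf-2 (9.62-fold). The list shifted by a median log2 of 1.07 (limma camera, adjusted p = 2.3e-10; adjusted p = 0.277 with an estimated correlation). Of 41 cytochrome P450 genes 10 rose and 2 fell (17 and 4 adjusted over the list alone), with a median of 0.71 (adjusted p = 7.9e-07; adjusted p = 0.277 with an estimated correlation). Of 45 glucuronosyltransferase genes 9 rose (12, with 1 lower, adjusted over the list alone), with ugt-2 at 21.3-fold and ugt-62 at 11.8-fold; their median was 0.57 (adjusted p = 1.2e-06; adjusted p = 0.277 with an estimated correlation). Of 28 glutathione S-transferase genes 5 rose (7 adjusted over the list alone), including gst-7 (4.07-fold, from 2357 ± 282 to 9623 ± 1452). Their median was 0.32 (adjusted p = 0.0047; adjusted p = 0.553 with an estimated correlation), and without wild-type spg-7 RNAi replicate 1 it was 0.05 and no longer called (adjusted p = 0.143). Of 18 genes of oxidative stress defence 3 rose (5 adjusted over the list alone): the metallothionein gene mtl-1 (log2 4.44, from a control signal under the filter level; 3.77 with 32 added and 3.73 without wild-type spg-7 RNAi replicate 1) and the superoxide dismutase genes sod-3 (3.46-fold) and sod-4 (2.22-fold), whose calls were each lost in 10 of the 12 fits without 1 array. The median of that list was 0.38 (adjusted p = 6.6e-04; adjusted p = 0.320 with an estimated correlation).

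The list of mitochondrial dynamics and mitophagy had a higher median in wild type and was the 1 list of 25 whose call held with an estimated correlation (median log2 0.86, camera adjusted p = 2.2e-05; adjusted p = 0.0348 with an estimated correlation). Of its 11 genes 4 rose (6 adjusted over the list alone) and 7 were not called. The 4 were mff-2, named for a mitochondrial fission factor (7.59-fold, from 533 ± 274 to 3723 ± 562), fis-2 (3.74-fold), drp-1, the dynamin of mitochondrial fission (3.01-fold, from 642 ± 57.2 to 1946 ± 306), and sqst-1, an autophagy receptor (4.07-fold; not called without wild-type spg-7 RNAi replicate 2, adjusted p = 0.0673). In a fit of the wild-type arrays alone drp-1 (limma adjusted p = 0.0536) and sqst-1 (0.126) were not called. Of 17 mitochondrial protein import genes 3 rose (4 adjusted over the list alone): timm-23 of the inner membrane translocase (2.45-fold), tomm-70 (2.18-fold) and timm-17B.1 (1.93-fold). These calls were lost in 2, 5 and 10 of the 12 fits without 1 array, timm-23 being not called without wild-type control RNAi replicate 3 (0.0684) or wild-type spg-7 RNAi replicate 2 (0.0616). The import list did not pass as a whole, with a median of 0.20 (adjusted p = 0.0569) that was -0.00 when arrays were scaled to control probe sets, which moves every gene alike and put the median of all genes at -0.25. Of 11 mitochondrial chaperone and protease genes none passed over all genes and 2 were higher adjusted over the list alone, D2030.2, a ClpX homologue, at 2.07-fold (adjusted p over all genes 0.0588) and C34C12.8, a GrpE homologue, at 1.58-fold (0.0695). Their median of 0.45 was called (camera adjusted p = 0.0042; adjusted p = 0.320 with an estimated correlation). Wild-type spg-7 RNAi replicate 3, at a median log2 signal of 10.36, lay within the range of the control arrays (10.27 to 10.51), and the other 2 were at 10.99 and 11.1198.

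Of 16 glycolysis genes 2 rose (also 2 adjusted over the list alone): ldh-1, lactate dehydrogenase (3.04-fold, from 2144 ± 350.3 to 6488 ± 833), and aldo-1, an aldolase (2.12-fold, a call lost in 8 of the 12 fits without 1 array). The glycolysis median was 0.47 (camera adjusted p = 0.0046; adjusted p = 0.329 with an estimated correlation), and it was 0.31 and not called without wild-type spg-7 RNAi replicate 1 (adjusted p = 0.0501). The 25 genes of the tricarboxylic acid cycle were not called (median -0.18, adjusted p = 0.0508). Of 36 nuclear genes of the respiratory chain and ATP synthase 1 fell, hpo-18 (log2 -0.64, lost in 11 of the 12 fits without 1 array), and none adjusted over the list alone. Their median was -0.21 (adjusted p = 0.0191; adjusted p = 0.703 with an estimated correlation), a call lost without wild-type control RNAi replicate 1, wild-type spg-7 RNAi replicate 2 or wild-type spg-7 RNAi replicate 3 (adjusted p 0.0553 to 0.380) or with each array centred on its median (-0.08, 0.0857). Of 62 genes of fatty acid desaturation and oxidation 3 rose and 3 fell, over all genes and adjusted over the list alone; the falls, acox-1.2, fat-7 and ech-1.1, were lost in 5, 8 and 11 of the 12 fits without 1 array, and the list was not called (median -0.14, adjusted p = 0.687).

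Cuticle collagens and body wall muscle genes had lower medians in wild type on spg-7 RNAi, called at the preset correlation only. Of 114 cuticle collagen genes 9 fell and none rose (9 adjusted over the list alone), for example col-156 (4.94-fold, from 3767 ± 712 to 824 ± 434) and col-89 (4.83-fold), calls that were lost in 5 and 9 of the 12 fits without 1 array. The median of the collagens was -0.98 (camera adjusted p = 5.7e-11; adjusted p = 0.320 with an estimated correlation), and their median log2 signal per array was 11.05, 11.56 and 11.99 on control RNAi and 10.49, 10.82 and 9.87 on spg-7 RNAi. Of 17 body wall muscle genes none passed over all genes and 4 were lower adjusted over the list alone. The median of the muscle genes was -0.55 (adjusted p = 2.8e-05; adjusted p = 0.387 with an estimated correlation), with the myosin gene myo-3 at 1411 ± 316 on control RNAi and 706 ± 211 on spg-7 RNAi (adjusted p over all genes 0.0613). The muscle call was lost without both wild-type control RNAi replicate 1 and wild-type spg-7 RNAi replicate 3 (-0.25, 0.129). The 33 proteasome genes had a median of -0.36 (adjusted p = 1.4e-04; adjusted p = 0.484 with an estimated correlation) and none of them passed, also adjusted over the list alone. Here too wild-type spg-7 RNAi replicate 3 (11.82) lay within the control arrays (11.80 to 12.01), with the other 2 at 11.28 and 11.42. None of the 74 cytosolic ribosomal protein genes passed either way. Their median was -0.24 (adjusted p = 2.0e-04; adjusted p = 0.732 with an estimated correlation), not called without wild-type control RNAi replicate 1 (0.135) or wild-type spg-7 RNAi replicate 3 (0.327). Quantile normalisation brought this median to -0.00 and ended the call (0.787), so the ribosomal shift depended on the scaling. Of the 13 lists called in wild type 7 had array medians that overlapped between the groups: chaperones and proteases, the respiratory chain, cytosolic ribosomal proteins, the proteasome, glutathione S-transferases, oxidative stress defence and muscle markers.

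The remaining lists were not called in wild type. No gene passed among 57 mitochondrial ribosomal proteins (median -0.05, adjusted p = 0.476), 20 genes of the endoplasmic reticulum unfolded protein response (-0.01, 0.995), 13 cytosolic heat shock genes (0.23, 0.220), 5 vitellogenins (1.95, 0.129), 23 major sperm proteins (-0.07, 0.995) and 21 oocyte and embryo markers (0.10, 0.962, where camera gave the direction as down). Adjusted over the list alone the count was 0 in each of these too. Of 14 stress-linked regulators 2 rose (3 adjusted over the list alone), atfs-1 and zip-3, both lost in 10 of the 12 fits without 1 array (median 0.17, adjusted p = 0.0824). Of 20 neuron markers 1 rose, snb-1 (1.79-fold; median -0.19, adjusted p = 0.476), and of 18 intestine markers 1 rose, ges-1 (2.94-fold; median 0.27, adjusted p = 0.165), each also 1 adjusted over the list alone. The calls of snb-1 and ges-1 were lost in 10 and 9 of the 12 fits without 1 array.

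In all, limma called 491 of 10385 genes in wild type at an adjusted p under 0.05: 342 rose, 318 of them at least 2-fold, and 149 fell, 135 of them at least 2-fold. In 489 of the 491 all 3 arrays of one group lay above all 3 of the other, as in 18.5% of all genes, where chance gives 10%. The count depended on single arrays, being 1039 without wild-type control RNAi replicate 1, 222 without wild-type spg-7 RNAi replicate 2 and 234 without wild-type control RNAi replicate 3, and it was 84 in a fit of the wild-type arrays alone. Of the rises named, that fit did not call clec-17, abf-2, drp-1, sqst-1, timm-23, tomm-70, timm-17B.1, aldo-1, atfs-1, zip-3, sod-3, sod-4, snb-1 and ges-1. Of the falls it did not call hpo-18, acox-1.2, fat-7, ech-1.1, col-156, col-89, F57H12.6, F20B10.3, cbs-2, cht-2, W04A4.2 and W03A5.1. With arrays scaled to hybridisation control probe sets, which moved the median of all genes from -0.04 to -0.25, 170 of 415 called genes rose. Among the genes named, drp-1, timm-23, tomm-70, timm-17B.1, aldo-1, atfs-1, zip-3, sod-3, sod-4, snb-1, ges-1, hpo-18, fat-7 and W04A4.2 were then not called.

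**Figure D3:**
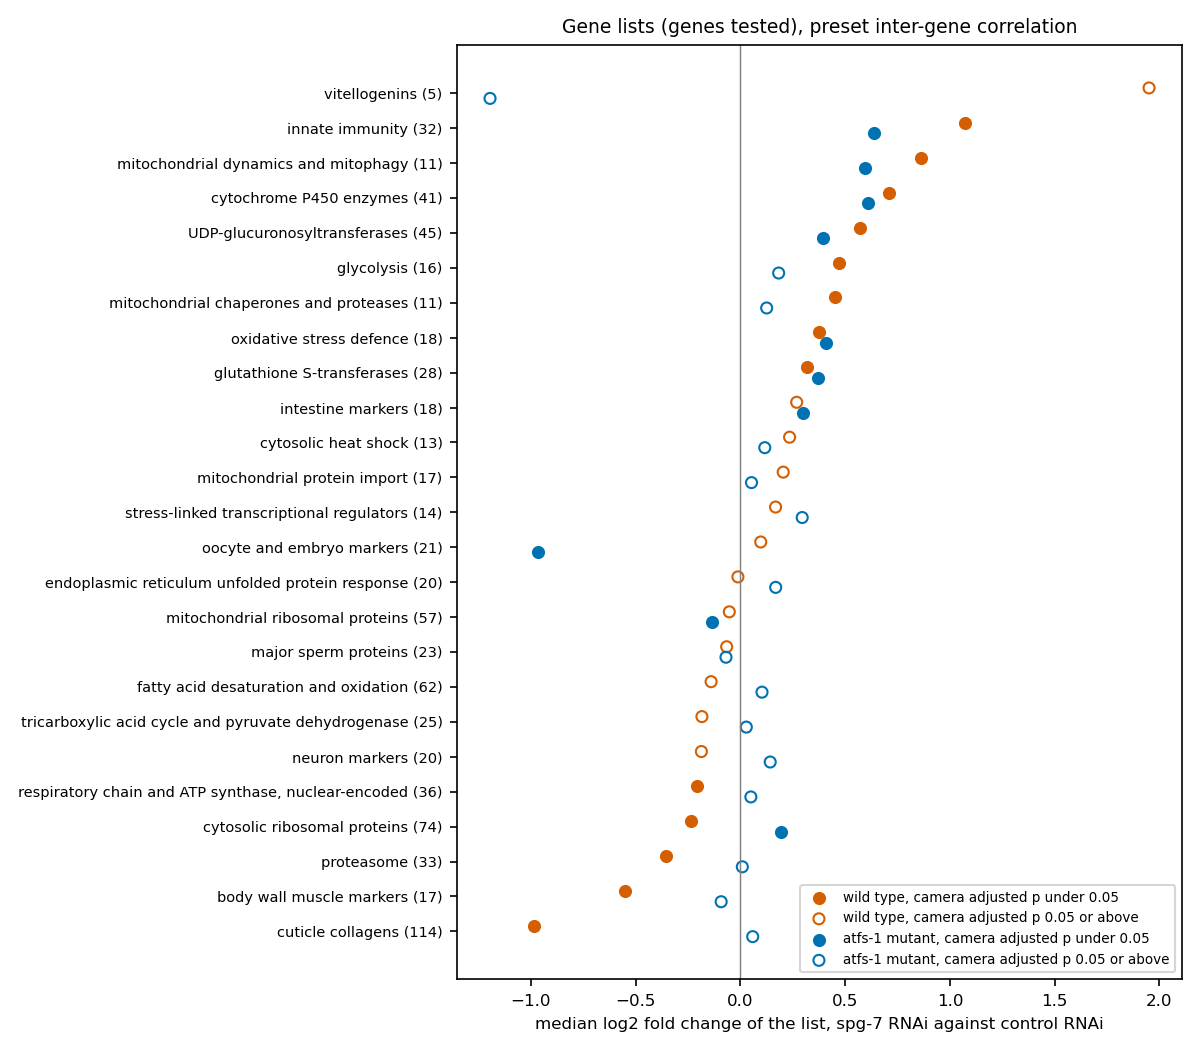
Median log2 change on spg-7 RNAi of each of 25 gene lists in wild type (orange) and in the atfs-1 mutant (blue), with the number of genes tested in brackets and filled points where the limma camera adjusted p was under 0.05 at the preset correlation. Mitochondrial dynamics and mitophagy in wild type (0.86) was the 1 filled point that held with an estimated correlation, and the 8 filled positive points of the mutant turned negative, at -0.12 to -0.56, when arrays were scaled to control probe sets, which moved every gene alike and the median of all genes to -0.77.

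The second comparison asks how atfs-1(tm4525) worms respond to spg-7 RNAi. Detoxification genes rose here too: cyp-13A5 from a signal of 16.3 ± 11.505 to 1267 ± 454 (SD, n = 3), cyp-33C8 from 275 ± 47.1 to 3790.2 ± 1322 (13.3-fold), ugt-2 from 262 ± 51.4 to 2386 ± 598 (9.06-fold) and gst-7 from 2258 ± 631 to 7860.4 ± 365 (3.57-fold). The tubulin gene tbb-6 rose 78.0-fold, from 154 ± 18.96 to 12577 ± 5117. F57B9.3 rose from 32.5 ± 16.05 to 894 ± 96.8. The falls that kept their calls whichever array was left out included Y49F6B.6 (from 396 ± 196 to 36.4 ± 14.2) and F58A4.1 (6.84-fold, from 649.7 ± 148 to 93.8 ± 10.29).

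The log2 rises were largest in cyp-13A5 (6.51, limma adjusted p = 8.8e-04), tbb-6 (6.29, 2.2e-06), spg-7 (5.46), cyp-13A8 (5.09, 0.0023), F57B9.3 (4.88, 2.2e-04), C08E8.4 (4.51, 0.0025), Y37H2A.14 (4.02), far-3 (3.89), ZK177.9 (3.89) and Y41C4A.32 (3.86). The control signal of cyp-13A5, cyp-13A8, F57B9.3 and ZK177.9 lay under the filter level. With 32 added before log2 they gave 4.71, 3.93, 3.87 and 3.2003. Without mutant control RNAi replicate 2 the change of cyp-13A5 was 5.88, and without mutant control RNAi replicate 3 that of C08E8.4 was 3.83. The call of far-3, a fatty acid and retinol binding protein gene, was lost in 4 of the 12 fits without 1 array. The 10 largest falls were in clec-92 (-4.34, adjusted p = 0.0455), clec-99 (-3.84), C16C8.9 (-3.62), tag-329 (-3.54), Y49F6B.6 (-3.40, 0.0043), pqn-84 (-3.28), C14F11.7 (-3.28), F56C3.8 (-2.93), F58A4.1 (-2.77, 0.0048) and clec-221 (-2.56). All but Y49F6B.6 and F58A4.1 lost their calls in 3 to 10 of those 12 fits, at adjusted p up to 0.236. With the replicate number as a block over all 12 arrays C16C8.9 (limma adjusted p = 0.0532) and clec-99 (0.0553) were not called. The spg-7 RNAi signal of clec-92, clec-99, tag-329, Y49F6B.6 and pqn-84 lay under the filter level. With 32 added they gave -3.59, -3.18, -2.87, -2.57 and -2.49. Mutant spg-7 RNAi replicate 2 mattered most for clec-99, at -2.97 without it, and for C16C8.9, at -2.90.

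By list, 10 of 25 were called in the mutant and none held with an estimated correlation, the lowest such adjusted p being 0.124. Scaling arrays to control probe sets moved every gene alike, with the median of all genes going from -0.02 to -0.77. The 8 lists called higher turned negative under it but stayed above -0.77. Of 41 cytochrome P450 genes 7 rose and none fell (14 adjusted over the list alone), with cyp-14A4 rising to a signal of 195 ± 71.1 from one under the filter level (log2 3.12, and 2.015 with 32 added), and their median was 0.61 (camera adjusted p = 5.1e-11; adjusted p = 0.124 with an estimated correlation), and -0.14 under that scaling against -0.77 for all genes. Of 45 glucuronosyltransferase genes 8 rose and 2 fell (8 and 3 adjusted over the list alone), ugt-19 rising 8.73-fold, with a median of 0.39 (3.7e-04), and -0.36 under that scaling against -0.77. Of 28 glutathione S-transferase genes 4 rose (6 adjusted over the list alone), gst-39 at 5.28-fold and gst-38 at 3.58-fold (lost in 8 of the 12 fits without 1 array, and with the replicate number as a block, adjusted p = 0.0505), with a median of 0.37 (1.6e-04), and -0.38 under that scaling against -0.77. For these 2 lists the adjusted p was 0.568 with an estimated correlation. No innate immunity gene passed, over all genes or adjusted over the list alone, with clec-4 at 641 ± 122 and 2766 ± 1588 (adjusted p = 0.176); the list median was 0.64 (3.7e-04; adjusted p = 0.568 with an estimated correlation), and -0.12 under control scaling against -0.77. Of the oxidative stress genes none passed (1 adjusted over the list alone), with a list median of 0.41 (3.7e-04; adjusted p = 0.568 with an estimated correlation) and -0.34 under control scaling against -0.77.

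Of the 11 genes of mitochondrial dynamics and mitophagy 1 rose in the mutant, fis-2 (3.97-fold, from 383 ± 57.8 to 1575 ± 585), and 3 adjusted over the list alone. Their median was 0.60 (camera adjusted p = 0.0020; adjusted p = 0.124 with an estimated correlation) and -0.16 under control scaling, where all genes had -0.77; sqst-1 stood at 3.34-fold with an adjusted p of 0.0658. None of the 21 oocyte and embryo markers passed either way, and all 21 had negative values, with a median of -0.97 (4.2e-04; adjusted p = 0.939 with an estimated correlation) that was -0.40 and not called without mutant spg-7 RNAi replicate 2 (0.0537). Medians of 0.19 in cytosolic ribosomal proteins (4.5e-04), -0.13 in mitochondrial ribosomal proteins (0.0224) and 0.30 in intestine markers (0.0231) were called with no gene passing either way, and each had an adjusted p of 0.939 with an estimated correlation. The cytosolic ribosomal call was lost without mutant control RNAi replicate 3 (0.338), under quantile normalisation (0.05, 0.163) and with the oocyte and embryo marker level as a covariate (0.04, 0.293). The mitochondrial ribosomal call was lost without mutant control RNAi replicate 3 (0.247), mutant spg-7 RNAi replicate 3 (0.0566) or wild-type control RNAi replicate 1 (0.0716), without both that array and wild-type spg-7 RNAi replicate 3 (0.0775), and with centred arrays (-0.11, 0.0514). The intestine call was lost without mutant control RNAi replicate 3 (0.149), mutant spg-7 RNAi replicate 1 (0.0850) or mutant spg-7 RNAi replicate 2 (0.0953), and with the covariate (0.14, 0.258). Control scaling gave -0.56 for the cytosolic ribosomal and -0.45 for the intestine list, against -0.77 for all genes. Array medians overlapped between the groups for 6 of the 10 lists, namely both ribosomal lists, innate immunity, oxidative stress defence, and oocyte and intestine markers. The other 15 lists were not called and held no gene that passed, over all genes or over the list alone. Among them were the mitochondrial chaperones and proteases (median 0.13, adjusted p = 0.505), protein import (0.05, 0.842), glycolysis (0.18, 0.127), the respiratory chain (0.05, 0.842), the proteasome (0.01, 0.953), cuticle collagens (median 0.06, mean -0.07, 0.842) and muscle markers (-0.09, 0.358).

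Limma called 121 genes in the mutant: 98 rose, 96 of them at least 2-fold, and 23 fell, all at least 2-fold. All 121 had non-overlapping groups, as had 25.9% of all genes, where chance gives 10%. The count was 44, 48, 50, 51 and 61 without mutant spg-7 RNAi replicate 2, mutant spg-7 RNAi replicate 1, mutant control RNAi replicate 1, mutant control RNAi replicate 3 and mutant control RNAi replicate 2, and 193 without wild-type control RNAi replicate 1. A fit of the mutant arrays alone called 320 genes, and one of the wild-type arrays alone 84. Which genotype had more calls thus depended on the fit. Scaling to control probe sets moved the median of all genes from -0.02 to -0.77 and left 31 calls, 16 up and 15 down; cyp-14A4, Y41C4A.32, ugt-21, ugt-62, gst-7, gst-38, gst-39 and fis-2 were then not called, nor were 6 of the falls named above.

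The third comparison asks whether the response to spg-7 RNAi differs between the mutant and wild type, which tests directly for dependence on ATFS-1. The rises in wild type were on the whole smaller in the mutant. Over the 342 genes that rose in wild type the median log2 change was 1.75 in wild type and 0.97 in the mutant, where 331 were positive and 310 were below their wild-type value; genes picked on the wild-type arrays are expected to lean this way. The largest such gaps were in cyp-14A4, at 3901 ± 1758 in wild type and 195 ± 71.1 in the mutant on spg-7 RNAi (difference of log2 responses -3.89 ± 0.64, SE), in slc-17.3, a transporter gene (-3.34 ± 0.58), and in irg-2 (-3.34). The wild-type control signal of all 3 lay under the filter level, so these sizes are uncertain. With 32 added before log2 they were -3.90, -2.81 and -2.51. The irg-2 signal was already higher in the mutant on control RNAi, without passing the test (values in the fourth comparison). Much of its gap is therefore a difference in the control signal. No single gene passed the test of this difference: limma called 0 of 10385 genes, with 647 at an unadjusted p under 0.05 where 519 are expected by chance, and the lowest adjusted p was 0.210.

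At that lowest adjusted p stood cyp-14A4, the innexin gene inx-9 (-2.64), the nuclear receptor gene nhr-61 (-2.13), slc-17.3 and Y58A7A.5 (-2.12); the last 4 were chosen after their values were seen. In central metabolism ldh-1 went from 2144 ± 350.3 to 6488 ± 833 in wild type and from 2671 ± 263 to 3011 ± 510.5 in the mutant (difference -1.44 ± 0.29, adjusted p = 0.448). The mitochondrial fission genes mff-2 (-1.78, adjusted p = 0.649) and drp-1 (-0.99, 0.714) and the import gene timm-23 (-1.06, 0.714) also had smaller values in the mutant, without passing the test. By contrast tbb-6 (0.46) and fis-2 (0.09) had responses of similar size, and of the 98 genes that rose in the mutant 39 had the larger and 59 the smaller value there. Between the lists called in wild type and in the mutant 87 genes rose in both, where 3.23 are expected by chance, and 5 fell in both, where 0.33 are expected. None moved in opposite directions, and 29 genes were called in the mutant and not in wild type; all 11 of those that rose also had positive values in wild type. Across genes, which are not independent replicates, the log2 changes of the 2 genotypes had a Pearson r of 0.42 and a Spearman rho of 0.37; r was 0.15 to 0.63 when 1 array was left out, lowest without wild-type control RNAi replicate 2 and highest without replicate 1.

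**Figure D4:**
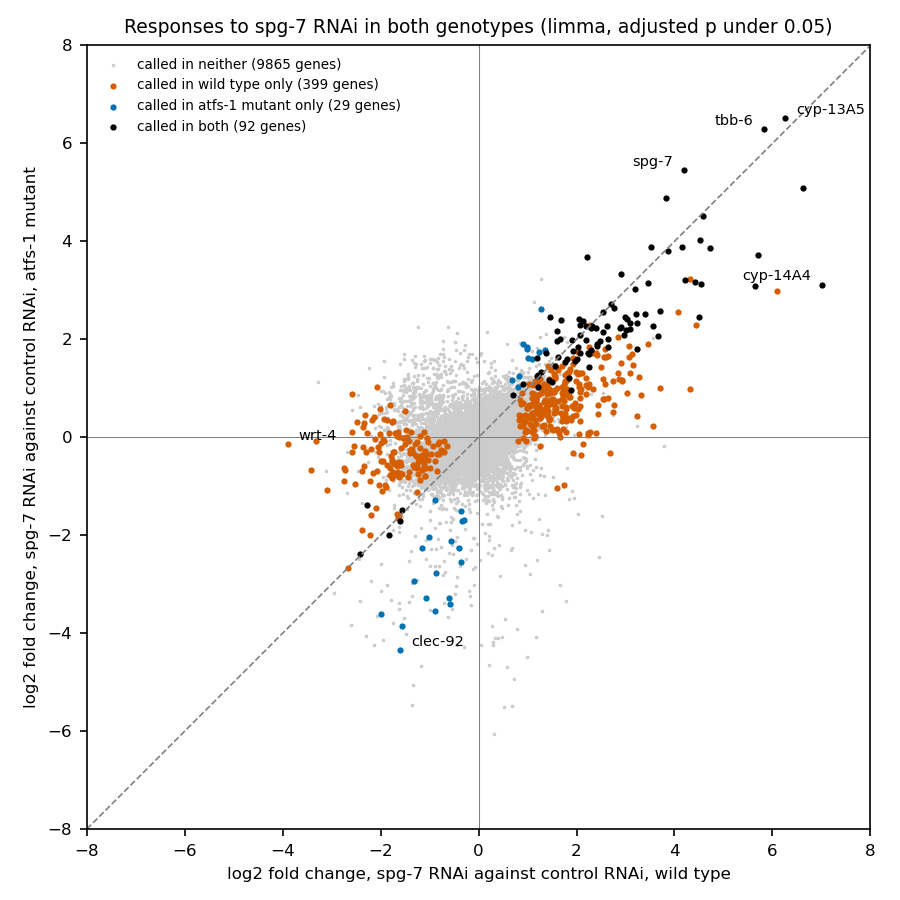
Log2 change on spg-7 RNAi in wild type (x axis) against the atfs-1 mutant (y axis) for 10385 genes, coloured by the genotype in which limma called them; the dashed line marks equal changes. Most of the 342 genes that rose in wild type lie under the line, while tbb-6 and spg-7 lie above it.

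By list, 11 of 25 differences were called by camera at the preset correlation and none with an estimated correlation, the lowest such adjusted p being 0.596. The response was lower in the mutant for innate immunity genes (median difference -0.45, adjusted p = 3.8e-05; 5 lower adjusted over the list alone), glucuronosyltransferases (-0.25, 8.2e-04; 4), mitochondrial chaperones and proteases (-0.29, 0.0185; 0) and mitochondrial dynamics and mitophagy (-0.29, 0.0188; 1, with 0 over all genes in each). It was higher for cuticle collagens (1.00, 3.2e-12), cytosolic ribosomal proteins (0.45, 3.2e-12), muscle markers (0.50, 2.3e-04), the proteasome (0.30, 5.9e-05) and the respiratory chain (0.24, 0.0092), with no gene passing either way. Scaling to control probe sets lowered every gene alike, the median of all genes going from -0.01 to -0.55. Of these 5 lists all but the collagens then turned negative (-0.04 to -0.30), and all stayed above -0.55. Quantile normalisation ended the ribosomal call (0.08, 0.0907) and the respiratory chain call (0.12, 0.108), so these depended on the scaling. With an estimated correlation the adjusted p of the 9 lists was 0.596 to 0.724. Yolk and oocyte genes differed as well, vitellogenins by -3.19 and oocyte and embryo markers by -1.21, and both calls were lost without wild-type control RNAi replicate 1 (-0.52 and -0.30), mutant spg-7 RNAi replicate 2 (-2.36 and -0.47) or wild-type spg-7 RNAi replicate 3 (-2.81 and -0.33), that of the vitellogenins also without wild-type spg-7 RNAi replicate 2 (-2.74). The chaperone call was lost without mutant spg-7 RNAi replicate 3 (-0.22), wild-type control RNAi replicate 2 (-0.16) or wild-type spg-7 RNAi replicate 1 (-0.25). That of mitochondrial dynamics was lost without mutant spg-7 RNAi replicate 3 (-0.40) or wild-type control RNAi replicates 1 (-0.25) or 2 (-0.43). That of the respiratory chain was lost without mutant spg-7 RNAi replicate 2 (0.18), wild-type control RNAi replicate 1 (0.19) or wild-type spg-7 RNAi replicate 3 (0.13), and that of the glucuronosyltransferases without wild-type spg-7 RNAi replicate 1 (-0.06). Without both wild-type control RNAi replicate 1 and wild-type spg-7 RNAi replicate 3 the muscle (0.15, 0.241), respiratory chain (0.08, 0.856), dynamics (-0.21, 0.0586), vitellogenin (-0.11, 0.856) and oocyte calls (0.38, 0.282) were lost. The marker covariate ended those of the respiratory chain (0.11, 0.164) and vitellogenins (-1.72, 0.133). Adjusted over the list alone 1 cytochrome P450 gene was higher and 3 were lower, and 1 glycolysis gene was lower, in lists that camera did not call. The number of genes called in the difference itself was 1, slc-17.3, without wild-type spg-7 RNAi replicate 3, and 1, cyp-14A4, with 32 added before log2.

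The fourth comparison asks what the atfs-1 mutation changes on control RNAi, and no gene passed. In the innate immunity list irg-2 stood at 52.7 ± 35.3 in wild type and 236 ± 49.6 in the mutant (SD, n = 3; log2 2.54, and 1.75 with 32 added, as the first signal was under the filter level), abf-1 at 4.14-fold and irg-1 at 3.06-fold, each with a limma adjusted p of 0.368. The glucuronosyltransferase gene ugt-29 was at 3.21-fold with the lowest adjusted p of all, 0.190. Limma called 0 of 10385 genes, with 1113 at an unadjusted p under 0.05 where 519 are expected by chance, and the groups did not overlap in 17.6% of genes, where chance gives 10%. The targeted gene atfs-1 differed by a log2 of 0.08 (adjusted p = 0.980), and hsp-6 and hsp-60 by 0.27 and -0.63 (0.859 and 0.450).

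Camera called 11 of 25 lists for the mutant against wild type on control RNAi, none with an estimated correlation (lowest adjusted p 0.801). Innate immunity was higher (median 0.41, adjusted p = 0.0036; 0 genes over all genes and 3 adjusted over the list alone), as were the glucuronosyltransferases (0.14, 0.0495; 0 and 5). Cytosolic ribosomal proteins were lower, with all 74 genes negative and none passing (-0.47, 1.2e-22), a median that shrank to -0.12 under quantile normalisation. Lower medians were also called for mitochondrial ribosomal proteins (-0.26), the respiratory chain (-0.17), the proteasome (-0.17), the tricarboxylic acid cycle (-0.09), cytosolic heat shock (-0.44), the endoplasmic reticulum unfolded protein response (-0.30) and collagens (-0.25). With arrays scaled to control probe sets, which moved every gene alike and the median of all genes from -0.02 to 0.43, these 7 turned positive (0.02 to 0.36) and stayed below that median. Quantile normalisation ended the calls of the proteasome (-0.15, 0.0602), the respiratory chain (-0.08, 0.210), the endoplasmic reticulum list (-0.24, 0.120), the tricarboxylic acid cycle (-0.06, 0.478), the collagens (-0.11, 0.715) and the glucuronosyltransferases (0.06, 0.120). The sperm proteins were higher by 1.03 and fell to 0.04, not called (0.815), without wild-type control RNAi replicate 1, the array that was lowest in sperm and yolk genes. Single arrays ended the calls of the tricarboxylic acid cycle, the glucuronosyltransferases and the collagens in 8, 7 and 7 of the 12 fits. The proteasome call was lost without wild-type control RNAi replicate 2 (-0.10), the heat shock call without mutant control RNAi replicate 2 (-0.36) and the endoplasmic reticulum call without wild-type control RNAi replicate 1 (-0.18), and the collagens turned positive (0.13) without mutant control RNAi replicate 3. Array medians of the 2 genotypes overlapped for 7 of the 11 lists, all but innate immunity, glucuronosyltransferases, mitochondrial ribosomal proteins and the proteasome.

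The fifth comparison asks what the mutation changes on spg-7 RNAi, where 10 genes passed. The largest difference was in cyp-14A4, 19.6-fold lower in the mutant (3901 ± 1758 in wild type, 195 ± 71.1 in the mutant; SD, n = 3; limma adjusted p = 0.0080), and its relative cyp-14A1 was 5.88-fold lower (2344 ± 504 and 407 ± 139; 0.0204). Also lower were nhr-61 (3.87-fold, 1074 ± 288 and 271 ± 15.3; 0.0204), inx-9 (5.53-fold, 1201 ± 352 and 213.8 ± 38.96; 0.0204) and the transporter genes slc-17.3 (log2 -2.56, 756 ± 489 and 111 ± 17.9; 0.04997) and slc-17.4 (3.73-fold; 0.0485). R08F11.4, Y37D8A.4 and F23F12.12 were lower by log2 values of -2.65, -2.49 and -2.14 (0.0209 each). F19H6.6 was the 1 gene higher in the mutant (5.97-fold, 100.5 ± 17.5 and 604 ± 138; 0.0209).

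All 10 had non-overlapping groups, as had 2389 of all 10385 genes, where chance gives 10%, and 1599 genes had an unadjusted p under 0.05. None of the 10 calls was stable: the count was 0 without mutant spg-7 RNAi replicate 1, wild-type spg-7 RNAi replicate 2 or mutant spg-7 RNAi replicate 3. It was 5 without wild-type spg-7 RNAi replicate 1 or mutant control RNAi replicate 2, 4 without mutant spg-7 RNAi replicate 2, 18 without mutant control RNAi replicate 3 and 587 without wild-type control RNAi replicate 1. Scaling to control probe sets ended 7 of the 10 calls, leaving those of cyp-14A4, cyp-14A1 and slc-17.3. The direction held, with cyp-14A4 between -4.86 and -3.95 over all settings. Among genes that did not pass, ldh-1 was at -1.11 (adjusted p = 0.0804), mff-2 at -1.76 (0.115), hsp-6 at 0.06 (0.934) and hsp-60 at -0.47 (0.411).

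Of 25 lists camera called 11 in this comparison, again none with an estimated correlation (lowest adjusted p 0.558). Lower in the mutant were protein import (median -0.31, adjusted p = 7.2e-04), mitochondrial ribosomal proteins (-0.30, 1.4e-06), mitochondrial chaperones and proteases (-0.26, 0.0188), glycolysis (-0.26, 0.0310), mitochondrial dynamics and mitophagy (-0.15, 0.0347), cytosolic heat shock (-0.56, 0.0023) and oocyte markers (-0.82, 0.0391). Higher were cuticle collagens (0.83, 1.2e-07), sperm proteins (1.01, 3.9e-04), fatty acid desaturation and oxidation (0.35, 0.0133) and muscle markers (0.32, 0.0106). Over all genes 0 members of these lists passed. Adjusted over the list alone 8 collagens, 2 fatty acid genes and 1 muscle gene were higher, and 2 dynamics genes and 1 gene each of import, chaperones and glycolysis were lower. Of 41 cytochrome P450 genes 2 passed, cyp-14A4 and cyp-14A1 (2 higher and 5 lower adjusted over the list alone), while the list was not called (median 0.14, mean -0.13, adjusted p = 0.659). Without wild-type spg-7 RNAi replicate 3 the fatty acid (0.06), muscle (0.10) and oocyte (-0.03) calls were lost. Those of chaperones, glycolysis and dynamics were each lost without wild-type spg-7 RNAi replicate 1 (-0.16, -0.13 and -0.33), wild-type spg-7 RNAi replicate 2 (-0.25, -0.19 and -0.12) or mutant spg-7 RNAi replicate 3 (-0.20, -0.15 and -0.10). The dynamics call was also lost without mutant spg-7 RNAi replicate 1 (-0.08) or wild-type control RNAi replicate 1 (-0.15), and the oocyte call without mutant spg-7 RNAi replicate 1 (-0.78), mutant spg-7 RNAi replicate 2 (-0.20) or wild-type spg-7 RNAi replicate 2 (-0.53). Quantile normalisation ended the chaperone (-0.23, 0.0662), dynamics (-0.25, 0.0577) and oocyte calls (-0.84, 0.0760). Centred arrays ended the muscle (0.09, 0.0646) and oocyte calls (-1.05, 0.159), and no filter the chaperone call (0.0522). Array medians of the 2 genotypes overlapped for 7 of the 11 lists, all but protein import, heat shock, sperm proteins and collagens.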

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

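Chosen after the result was seen were the tests of explanations for the spg-7 signal, the bound for single arrays in the collagens, every use of the marker covariate, scaling to control probe sets and the tests of control probe sets.

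For 11 gene lists the response to spg-7 RNAi differed between the mutant and wild type by a test of the difference itself (camera in limma at a preset correlation). The median log2 difference, mutant minus wild type, was -0.29 for mitochondrial chaperones and proteases, -0.29 for mitochondrial dynamics and mitophagy, -0.45 for innate immunity, -0.25 for glucuronosyltransferases, -1.21 for oocyte and embryo markers and -3.19 for vitellogenins. It was 0.24 for the respiratory chain, 0.45 for cytosolic ribosomal proteins, 0.30 for the proteasome, 1.00 for cuticle collagens and 0.50 for muscle markers. Adjusted p values were 3.2e-12 to 0.0247 and, with an estimated correlation, 0.596 to 0.724, so none holds once genes of a list are taken to move together. Scaling to control probe sets moved every gene alike, the median of all genes going from -0.01 to -0.55, and the respiratory chain, ribosomal, proteasome and muscle medians turned negative (-0.30, -0.10, -0.24 and -0.04) but stayed above it. Under quantile normalisation the ribosomal (0.08, 0.0907) and respiratory chain (0.12, 0.108) differences were not called. Without wild-type control RNAi replicate 1 the vitellogenin difference was -0.52 (adjusted p = 0.424) and that of the oocyte markers -0.30 (adjusted p = 0.254).

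Signal outside the comparisons was seen in control probe sets, whose group means were higher on spg-7 RNAi than in the control samples, with no p under 0.05. Wild-type spg-7 RNAi replicate 3 did not share this. Its mean log2 signal for the hybridisation controls was 10.27, within the range of wild-type control RNAi replicates 1, 2 and 3 (10.90, 10.26 and 10.83). Hybridisation controls, meant to be added in equal amount to each array, were higher by a log2 of 0.21 in wild type and 0.75 in the mutant (exact two-sided permutation test, p = 0.5 and 0.2; smallest possible 0.1). Controls added to the RNA before labelling were higher by 0.67 and 1.28 (exact p = 0.5 and 0.2). These tests did not use the replicate numbers. In the mutant every spg-7 RNAi array lay above the control array of its number, for both kinds of controls. Over both genotypes the differences were 0.48 (exact p = 0.08) and 0.97 (exact p = 0.075). Of 677 probe sets with several or no gene names, limma called 15 higher and 18 lower in wild type and 6 higher and 2 lower in the mutant.

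The first pattern weighed was the higher spg-7 signal on spg-7 RNAi. Single swapped arrays are argued against, since the lowest spg-7 RNAi array lay 2.78 (log2) above the highest control array. An exchange of the labels of all arrays would leave the same gap and stays open. A rise that needs ATFS-1 is argued against by a mutant response that was not smaller (difference 1.27 ± 0.64, SE). RNA from the feeding clone, which carries spg-7 sequence, is a candidate explanation that the values fit, as the highest change of any other mitochondrial chaperone or protease gene in either genotype was 1.05. A feedback specific to the spg-7 gene would look the same and stays open, and so does the depth of the knockdown.

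The second pattern was the lower signal of cuticle collagens on spg-7 RNAi in wild type, a shift of -0.98. A single array as the cause is argued against, as the median closest to 0 with 1 array left out was -0.78. Collagen genes are expressed in waves with each moult, so cultures of different age could give such a shift. With the oocyte and embryo marker level of each array as a covariate the median was -0.998, but within groups the collagens did not follow these markers (r = -0.003), so the covariate could not have removed an effect of age. Age and the RNAi treatment cannot be told apart here, because the age of the cultures was not measured in another way. No list of moulting cycle markers was among the lists tested. The families given under other observations were formed by gene name only. Neither they nor single genes were sorted by the moulting cycle.

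The third pattern was that rises in wild type were larger than in the mutant. Picking genes on the wild-type arrays would give such a gap, and a test on arrays left out of the picking gave a larger wild-type median in 8 of 9 cases, the exception being wild-type control RNAi replicate 1 with wild-type spg-7 RNAi replicate 3 (0.59 against 0.76). That falls short of the 9 set in advance, so selection as the whole cause cannot be told apart from a real gap, although the mean on left-out arrays was 1.78 against 1.16 in the mutant. Different age of the cultures was weighed with the marker covariate. The mutant to wild-type ratio of medians was 0.49 with the covariate (0.46 to 0.55 with 1 array left out) and 0.55 without. Within groups these genes did follow the markers (r = -0.69), so the covariate could remove an effect that follows them, and the ratio did not rise. Picking genes on the wild-type arrays lowers this ratio with or without the covariate, and age that oocyte markers do not track, as for the collagens, was not covered. The ratio can therefore not decide on age, which stays open beside selection. Dependence on ATFS-1, the biological difference in the design, stays a hypothesis, with 0 genes called by limma in the difference and 647 at an unadjusted p under 0.05.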

How the results depend on the processing

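The settings that left out 2 wild-type arrays, used the marker covariate or scaled to control probe sets were chosen after the data were seen. Of 5484 single-gene log2 values under the alternatives 4877 kept direction and side of the threshold, 445 lost the call and 130 gained one. In 32 the sign changed without a call in either fit, and in 0 it changed with a call. Of 1064 list tests 886 kept both, 170 lost the call and in 8 the direction by camera reversed. These list tests did not include scaling to control probe sets, which moves all genes alike. Comparisons are in the order wild-type response, mutant response, difference of responses, mutant against wild type on control RNAi, and on spg-7 RNAi (491, 121, 0, 0 and 10 genes). With 1 array left out they called 222 to 1039, 44 to 193, 0 to 1, 0 to 0 and 0 to 587 genes. Genes higher in wild type with a called smaller response in the mutant were 0 to 1, and r between responses was 0.154 to 0.627; lists called were 12 to 17, 8 to 10, 8 to 14, 8 to 13 and 7 to 14. Array weights, whose estimation did not converge, gave 1785, 1532, 96, 519 and 710 genes and 65 with a smaller response. With 32 added the difference had 1 gene, also 1 with a smaller response. No filter gave 18 genes on spg-7 RNAi and r 0.293. Leaving out the lowest 60% gave 71 in the mutant. Fits to the groups of a comparison only gave 84 and 320 for the 2 responses. A random replicate block gave 16 on spg-7 RNAi, and a fixed replicate block 532, 106, 0, 0 and 7. In the mutant response this block, set on wild-type and mutant arrays alike, ended the calls of C16C8.9, clec-99 and gst-38. It changed no other call of a named gene or list there. In the other comparisons of groups the lowest r of a same-numbered pair was -0.101, -0.462 and -0.0911, and of 12 arrays 6 correlated best with their own number. An adjusted p under 0.01 left 154, 48 and 1 (spg-7 RNAi), by its own construction. Both arrays out (wild-type control 1, wild-type spg-7 3) gave 1227, 247 and 240 (spg-7 RNAi) and r 0.719; the covariate gave 1267, 535 (spg-7 RNAi) and r 0.556; control probe set scaling gave 31 in the mutant and 4 on spg-7 RNAi. Quantile normalisation left 6 lists on control RNAi, and an estimated correlation left 1, 0, 0, 0 and 0. With both arrays out list medians changed sign in wild type for the respiratory chain (0.0519) and cytosolic ribosomal proteins (0.0290), and in the difference for oocyte markers (0.38). Camera's direction alone reversed between genotypes for sperm proteins on control RNAi (median 0.0359) and oocyte markers on spg-7 RNAi (-0.0320), whose medians shrank but kept their sign. These 2 had the same values also without wild-type control RNAi replicate 1 and without wild-type spg-7 RNAi replicate 3. With 1 array left out sperm proteins reached 1.52, oocyte markers -1.97, and collagens on control RNAi ran from -0.42 to 0.13 (without mutant control RNAi replicate 3). Except for the stricter threshold, the cause was not tested. Precision is limited by 3 arrays per group, and for dim genes by signal near background.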

Other observations

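Families were examined after the data had been seen: 102 families of gene names with at least 10 genes tested, with camera in limma adjusted over the families. In the wild-type response nuclear hormone receptor (nhr) genes were higher, 15 called higher and 1 lower of 110 (median log2 0.42, adjusted p = 1.7e-07; adjusted p = 0.875 with an estimated correlation), and 5 of 10 abu genes were called lower (-1.77, 2.0e-07; 0.663 with an estimated correlation). Of 56 F-box A (fbxa) genes 5 were called higher (0.35, 0.0016; 0.175). Of the families lower in wild type, col and abu had the lowest adjusted p. Next were idpp (-1.17, 9.3e-05, and 0.806 with an estimated correlation) and nas (-1.03, 0.0019, and 0.745). In the mutant 2 nhr genes were called higher (0.40, 2.0e-07; 0.990), and the nhr median turned negative there (-0.36) under scaling to control probe sets, which moved every gene alike and the median of all genes to -0.77. Single arrays moved the nhr medians, to 0.25 without wild-type spg-7 RNAi replicate 1 and 0.63 without replicate 3 in wild type, without ending a call. Between the genotypes on control RNAi the spe genes of spermatogenesis were higher in the mutant (1.29, 7.0e-11; 0.794), as on spg-7 RNAi (1.302, 2.1e-06; 0.721), with 0 called by limma. Without wild-type control RNAi replicate 1, the array lowest in sperm proteins, the first of these medians was 0.62 (1.1e-06). In the difference between responses camera gave the lowest adjusted p to col (0.81, 1.2e-07), rpl (0.45, 1.2e-07), bus (1.66, 4.0e-07), rps (0.43, 5.9e-07) and abu (1.37, 9.1e-07). These had the higher response in the mutant. Next were clec (-0.64, 2.4e-06) and idpp (1.37, 4.1e-06), with 0 genes called by limma. No family held with an estimated correlation.

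Tests of regrouped arrays for the difference between responses, for genes with a smaller response in the mutant and for the mutant against wild type on control RNAi were chosen after the result was seen; those for the other 3 comparisons were set before. In wild type 1 of 10 splits of the 6 arrays gave as many genes as the real 491, the real one itself, and the highest other was 330; in the mutant 1 of 10 did (121, highest other 0), and on spg-7 RNAi between genotypes 1 of 10 (10, highest other 0). In the mutant 0 genes were called by the 3 other splits that part all 3 same-numbered pairs, and by the 6 that part 1. In each of these 3 comparisons there are too few splits for a share under 0.05. Where the real count is 0 the outcome is fixed in advance and says nothing about chance. This holds for the genotypes on control RNAi (10 of 10, highest other 0; 1113 genes at an unadjusted p under 0.05 by limma), for the difference between responses (100 of 100, highest other 740) and for a smaller response in the mutant (100 of 100, highest other 316). The split with 330 genes set wild-type control RNAi replicate 1 with wild-type spg-7 RNAi replicates 1 and 3. The other arrays of that split kept their RNAi sides except wild-type spg-7 RNAi replicate 2, so the RNAi response can contribute to it. What gave these 330 genes, and the 740 of a regrouping, was not tested.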
